A study of Mus musculus with 3 samples.

How the data were processed

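Total RNA of whole kidney was hybridised to 3 arrays of 2 colours. Per the labels, RNA of nephritic BALB/c mice taken 11 days after injection of anti-GBM antibody carried Cy5, and RNA pooled from the kidneys of 5 normal BALB/c mice carried Cy3. Each array's label names a different mouse, so the 3 arrays were treated as 3 animals, numbered by the replicate number in the label. Dyes were not swapped. The control pool was on every array and counts as 1 control sample, so the ratio against 0 was the test, which leaves out the spread between control mice and any dye bias.

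The values used were the deposited log ratios, 1 column per array and 16281 rows. The scanner, the normalization, the base of the logarithm and the direction of the deposited ratio are not given in the sources used here. Both signs occur, and the values run from -2.89 to 3.27, so they are on a log scale. The largest, 3.27, would be a 9.63-fold change in base 2, 26.2-fold in natural base and 1850-fold in base 10. The typical difference between 2 mice would be 1.12 to 1.20-fold, 1.18 to 1.30-fold and 1.47 to 1.82-fold. The base was left open, values are given in the deposited log unit, and a count of genes changed by at least 2-fold was not made. Cy5 over Cy3 was taken as the likely direction from the dye labels and from textbook genes of injured and healthy kidney.

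The median of each column over all cells was 0, and over the cells other than 0 it was 0.0151, 0.0160 and 0.0171 in mice 1, 2 and 3, with SDs of 0.459, 0.461 and 0.438, so the deposited arrays look centred. Exact 0 filled 5043, 5283 and 4351 cells (31.0, 32.4 and 26.7%), and 3173 rows were 0 on all arrays, among them rows of Umod and Kap, which normal kidneys make in large amounts. Exact 0 was therefore treated as missing, a choice made after the values were seen. The number of arrays limits the precision, and signal over background was not analysed here.

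Gene names came from the platform annotation, brought up to date through gene identifiers in a RefSeq table of mouse assembly GRCm38.p6, which was used for names only. Of the rows, 13738 had 1 gene symbol (13694 of them in the RefSeq table), 52 had several and 2491 had none; a row with several or none stayed an unnamed feature. No genome build was named for the array, so no coordinates are given. Each array was centred on its median, rows of a gene were averaged (1139 tested genes had over 1 row), and features with a ratio on all 3 arrays were tested: 8449 in all, 7211 named genes and 1238 unnamed features.

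Tests were made in R 4.3.3 with limma 3.58.1: lmFit with an intercept, eBayes (prior SD 0.134 with 4.85 prior degrees of freedom, beside 2 residual), two-sided, and Benjamini-Hochberg adjustment at 0.05. Adjusted p-values of genes are from this model. Camera with a preset inter-gene correlation of 0.01 tested 25 gene lists of at least 5 measured members against all other features, adjusted over the lists, which cover complement, MHC class I and II, interferon, NF-kB, chemokines, leukocyte types, erythroid cells, matrix, tubular injury, acute phase, podocytes, endothelium and mesangium, nephron segments, fatty acid and mitochondrial metabolism, cell cycle, ribosome, oxidative stress, surrounding tissue and sex. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The rule took, among genes passing with the same sign in all mice, the 12 highest and the 12 lowest, plus up to 4 members of each list with the smallest p and the genes used to check the direction; a few further members that went against their list were named after their values were seen.

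Alternatives were no centring, scaling of arrays to the same median absolute value, rows tested singly, ratios on at least 2 arrays, a robust prior, array weights, an unmoderated one-sample test, leaving out the 20% of features with the lowest SD, each mouse left out, and for lists an estimated correlation, ranks, fry (which tests whether a list moves one way, without comparing it with other genes) and leaving out members of several lists. With an estimated correlation camera also uses only the 2 residual degrees of freedom, so a call lost there need not come from correlation among members. Keeping exact 0 as a ratio and leaving out a run of neighbouring low rows were added after the data were seen. The scaling was planned as limma's normalizeBetweenArrays with method scale, which gave no values on a plain matrix of ratios with medians near 0. Its step for 2-colour ratios, normalizeMedianAbsValues, was used in its place, and the largest difference between the values of the 2 calls was 0. No table of scanner values was used here.

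The scripts were tested on simulated data with 8449 features, 200 of them changed, for the comparison of nephritic mice with the pool. With no spread in the pool, 68% of changes of 0.5 and 100% of changes of 1 were recovered in 176 calls, of which 4.55% were false. With a pool of 5 mice that vary like the others, 72% and 98% were recovered in 209 calls. Of these calls 18.7% were false, an excess that the adjusted p-values here do not cover. Each setting was drawn once, with 200 changed features, whereas 3638 of 8449 features passed in the data. The share of false calls depends on how many features change, so 18.7% is no estimate of the share in the data. All 3 lists shifted by 0.5 were called, and 0 of 19 lists without shifted members. The simulated genes varied independently of each other, with no spread in the pool for the lists. This does not cover false calls of lists whose members are correlated, where the estimate reached 0.744 for MHC class II.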

Results

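Kidney RNA from mice with anti-GBM glomerulonephritis, an immune injury of the glomerular filter caused by antibody against the glomerular basement membrane, was compared with RNA from normal kidneys of the same BALB/c strain. Each of 3 arrays held labelled RNA of 1 nephritic mouse, taken 11 days after antibody injection, beside the same pool of kidney RNA from 5 normal mice. The value table had 16281 rows, and an array gave a usable ratio for 11238 rows in mouse 1, 10998 in mouse 2 and 11930 in mouse 3. All values below are log ratios in the deposited log unit, whose base was not stated, so a value of 1 stands for a 2-fold change if the base is 2, for 2.72-fold if it is natural and for 10-fold if it is 10. Positive values are taken as higher in nephritic kidney, a direction that is likely from the dye labels but is not stated for the values.

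Across the 9693 rows with a ratio on all arrays, Pearson's r was 0.802 between mice 1 and 2, 0.851 between mice 1 and 3 and 0.906 between mice 2 and 3, and Spearman's rho was 0.718, 0.766 and 0.857. Genes are not independent replicates and the shared control pool raises these correlations, so no p-value was attached to them. Simulated arrays with no changed gene and a shared pool of 5 mice gave r between 0.101 and 0.183, which leaves out any dye bias shared by the arrays. Of the 9 measured genes used to check the direction, the 7 genes of inflamed or injured kidney were higher and the 2 genes of healthy tubules were lower in all 3 mice. The extracellular matrix protein fibronectin, Fn1, was at 2.19 ± 0.298 (SD, n = 3), the protease inhibitor Timp1 at 1.53 ± 0.223 and the filament protein vimentin, Vim, at 1.05 ± 0.0805. Lower values came from the phosphate transporter Slc34a1 at -1.22 ± 0.278 and the growth factor Egf at -1.14 ± 0.154; both moved, to -0.71 and -0.56 with exact 0 values kept as ratios. The genes were picked because textbooks give their direction, and they are not independent evidence of it. All 9 also belong to gene lists tested below.

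The question of the design was which kidney genes differed at day 11 of the nephritis. The 12 highest genes included 2 genes of matrix proteins and 3 of chemokines. Col3a1, a collagen of fibrous tissue, stood at 2.43 ± 0.716 (SD, n = 3), with mouse 1 at 3.25, and Fn1 followed at 2.19. The calcium-binding protein S100a6 rose by 2.35 ± 0.137 and Sox9, a transcription factor of regenerating tubules, by 2.31 ± 0.136. The chemokines Ccl20 and Cxcl2 rose by 2.20 ± 0.111 and 2.07 ± 0.105, the platelet chemokine Pf4 by 2.19 ± 0.343. The leukocyte adhesion molecule Vcam1 rose by 2.14 ± 0.232 and the alarm cytokine Il33 by 2.04 ± 0.637. Clca3a2 at 2.40 ± 0.484, the fungal glucan receptor Clec7a at 2.00 ± 0.453 and Trim59 at 1.99 ± 0.324 complete the 12 highest genes. Adjusted p-values of these 12 ran from 3e-05 to 0.000458. With exact 0 values kept as ratios, an alternative added after the data were seen, 6 of them lost the threshold (Col3a1, Clca3a2, S100a6, Cxcl2, Il33 and Clec7a). In that setting S100a6, Ccl20, Pf4 and Cxcl2 moved to 1.03, 1.11, 1.10 and 0.89. Col3a1, Clca3a2, Il33 and Clec7a kept nearly the same values (Col3a1 2.44), so zeros in their own rows did not cost them the threshold.

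Among the 12 lowest genes, the organic anion transporter Slco1a6 was at -2.40 ± 0.264, the milk protein gene Lalba at -2.34 ± 0.246 and Igfbpl1 at -2.20 ± 0.0825 (SD, n = 3). Albumin, Alb, was at -2.06 ± 0.449, the pyrimidine-degrading enzyme Dpys at -2.01 ± 0.261 and the muscle myosin Myh1 at -1.95 ± 0.368. Nepn was at -2.12 ± 0.499, Tex47 at -2.06 ± 0.333 and Capn15 at -1.92 ± 0.65. The other lowest genes, Sdc3 at -2.40 ± 0.43, Hes1 at -2.22 ± 0.358 and Lhx1 at -2.04 ± 0.115, sat in a run of 16 neighbouring row IDs, picked out after the values were seen, in which 10 of the 11 rows measured on all arrays lay at -1 or less. Each of the 12 lowest genes rested on 1 row with a ratio on all arrays, as did each of the 12 highest except Clec7a, with 2. With exact 0 values kept, 5 of the 12 lowest lost the threshold (Sdc3, Nepn, Alb, Myh1 and Capn15), and Capn15 moved to -0.95. For 34 rows outside that run with a mean of -1 or less and a second row of the same gene, the second row was at least 0.5 times as far from 0 in 7, or 20.6%, against 62 of 78 rows, or 79.5%, with a mean of 1 or more. Since both rows of a gene could enter these counts, they were repeated with 1 row per gene, the farthest from 0. This gave 6 of 33 genes, or 18.2% (exact 95% interval 6.98 to 35.5%), for falls and 38 of 54, or 70.4% (56.4 to 82%), for rises (Fisher's exact test, two-sided, p = 2.36e-06). The genes without such a second row numbered 27 for falls and 16 for rises. These counts of second rows and their test were chosen after the values were seen.

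**Figure D1:**
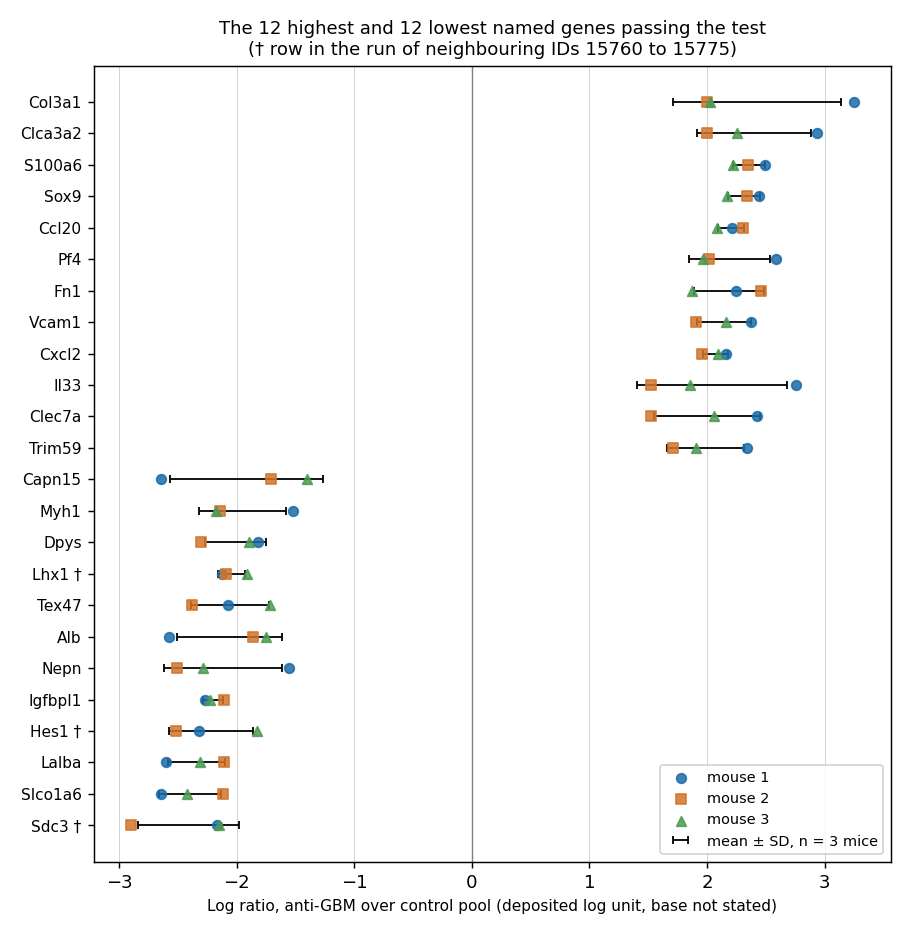
Log ratios of the 12 highest and the 12 lowest named genes that passed the test, on the x axis in the deposited log unit. Each symbol is 1 mouse, bars give the mean ± SD of 3 mice, and daggers mark Sdc3, Hes1 and Lhx1, which sit in the run of neighbouring low rows; Col3a1 in mouse 1, at 3.25, is the highest point.

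**Figure D2:**
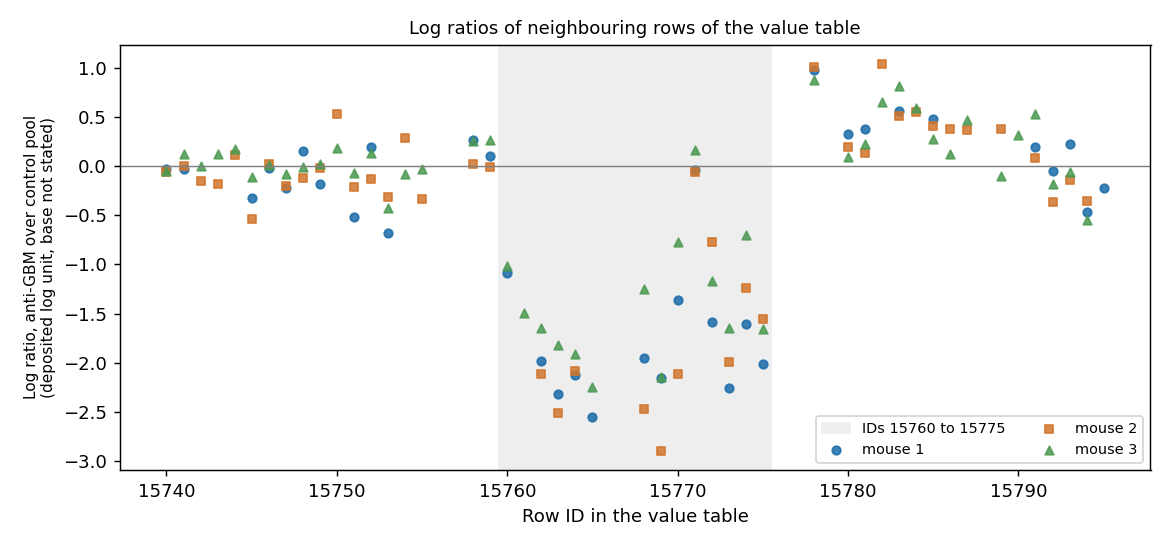
Log ratios (y axis, deposited log unit) of rows in and around a run of 16 neighbouring IDs (x axis, row ID), with 1 symbol per mouse and row. Inside the shaded run 10 of the 11 complete rows have a mean of -1 or less, and Nxf1, at 0.02, is the exception.

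Over the whole table, 3638 of 8449 tested features, 43.1%, passed at an adjusted p of 0.05, with 1755 higher and 1883 lower. Which side was larger turned without centring (1863 higher and 1730 lower), with exact 0 values kept (549 and 437) and without mouse 2 (1348 and 1310). Of the 7211 named genes, 1532 were higher and 1579 lower. Rises of at least 1 numbered 179 and falls 112, those of at least 1.5 were 51 and 25, and those of at least 2 were 11 and 10. The test was limma's moderated test of the 3 ratios against 0, which leaves out the spread between control mice and any dye bias. An unmoderated one-sample test passed 0 features (3060 at an unadjusted p under 0.05, against 4361 for limma). The count fell to 986, of which 900 were shared, when exact 0 values were kept as ratios, and to 2202 without mouse 3. Keeping exact 0 raised the features tested to 13241, and rows holding 0 then entered the averages of their genes. Limma's prior and the adjustment then also rested on rows that were 0 on all arrays, and the smallest adjusted p rose from 3e-05 to 0.00908. A gene could thus lose its call with its own ratios unchanged except for the centring, as Col3a1 did (limma adjusted p = 0.0845). With exact 0 kept, 38 of the 110 genes named by the rule and 22 of the 31 named after their values were seen lost the threshold.

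Genes of macrophages and dendritic cells rose together. Of 33 measured members, 29 rose and 0 fell, with 4 not passing, and the list mean was 0.95, between 0.871 and 1.03 in the 3 mice. The lysozymes Lyz2 and Lyz1 rose by 1.69 ± 0.0986 and 1.53 ± 0.0486 (SD, n = 3), Ncf4, a part of the phagocyte oxidase, by 1.74 ± 0.153 and Ms4a6d by 1.47 ± 0.0535. Ncf4 moved to 0.92 when ratios on 2 arrays sufficed, and to 0.65 with exact 0 values kept, where its call was lost (adjusted p = 0.0849). Camera gave an adjusted p of 1.02e-14, and the adjusted p was 0.223 with an estimated correlation; 31 rose when adjusted over the list alone.

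Antigen presentation genes were higher as well. Of 8 MHC class II genes, 7 rose, among them the protease Ctss at 1.83 ± 0.194, H2-Aa at 0.95 ± 0.175, H2-Ab1 at 0.94 ± 0.178, H2-DMa at 0.77 ± 0.106 and the invariant chain Cd74 at 0.82 ± 0.292 (SD, n = 3). Ciita, their transcriptional master regulator, named after its value was seen, stood at -0.07 ± 0.178 and did not pass (adjusted p = 0.52), and it moved to -0.17 without mouse 1 and to 0.00367 without mouse 2. Keeping exact 0 values ended the calls of H2-Aa, H2-Ab1 and Cd74. The list mean was 0.88 (adjusted p = 7.69e-05, and adjusted p = 0.315 with an estimated correlation; 7 rose adjusted over the list alone). Of 20 MHC class I and antigen processing genes, 16 rose and 0 fell, including H2-K1 at 0.89 ± 0.082, H2-D1 at 0.81 ± 0.035 and the immunoproteasome subunits Psmb8 at 1.02 ± 0.189 and Psmb10 at 0.75 ± 0.0537. H2-K1 moved to 0.50 with exact 0 values kept, where Psmb8 lost its call. Their mean was 0.51 (adjusted p = 1.19e-07, and adjusted p = 0.223 with an estimated correlation; 18 rose adjusted over the list alone). Interferon response genes rose in 23 of 30 and fell in 0, and the 4 with the smallest p were Ifi204 at 1.26 ± 0.187, the RNA sensor Oas1a at 1.09 ± 0.226, the GTPase Gbp2 at 0.72 ± 0.144 and Rtp4 at 0.61 ± 0.0563, of which Oas1a and Gbp2 lost their calls with exact 0 values kept. This list had a mean of 0.46 (adjusted p = 8.17e-08, and adjusted p = 0.283 with an estimated correlation; 24 rose adjusted over the list alone).

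Chemokine and NF-kB genes rose, with exceptions. Of 34 chemokines and receptors, 23 rose and 4 fell, and the list mean was 0.57. Beside Ccl20 and Cxcl2 the neutrophil chemokine Cxcl1 rose by 1.31 ± 0.0649 and the decoy receptor Ackr1 by 1.69 ± 0.134 (SD, n = 3), which moved to 0.66 and 0.83 with exact 0 values kept. The 4 that fell were Ccr3, Cxcl12, Ccl27a and Cxcr2, at -0.77, -0.83, -0.56 and -0.31, named after their values were seen. Cxcr2 lost its call without mouse 3 (-0.31, adjusted p = 0.0737), and with exact 0 values kept Cxcl12 and Cxcr2 moved to -0.39 and -0.20 and all 4 lost theirs. The list's adjusted p was 9.25e-07, and the adjusted p was 0.228 with an estimated correlation; 24 rose and 4 fell adjusted over the list alone. Of 33 NF-kB targets and signalling genes, 20 rose and 3 fell, with a mean of 0.65 and the cytokine Il6 at 1.87 ± 0.064. The 3 that fell, also named after their values were seen, were the inhibitors Nfkbib at -1.92, which sits in the run of low rows, and Nfkbie at -0.69, and the kinase subunit Ikbkg at -0.30, a call lost without mouse 2 or mouse 3 (-0.28 and -0.29) and with exact 0 values kept. The adjusted p was 2.05e-07, and the adjusted p was 0.223 with an estimated correlation; 21 rose and 3 fell adjusted over the list alone, and 8 of the 33 members belong to another list.

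Complement genes rose in 9 of 17, with 1 fall, C9 at -0.35, named after its value was seen. Without mouse 2 it moved to -0.23 and lost its call (adjusted p = 0.147), which was also lost without mouse 3 (-0.33, adjusted p = 0.116) and with exact 0 values kept. The regulator Cfi rose by 1.61 ± 0.197, the first-component subunits C1qa and C1qc by 1.22 ± 0.115 and 1.32 ± 0.201 and C4b by 1.21 ± 0.133 (SD, n = 3). The mean was 0.49 (adjusted p = 0.00375, and adjusted p = 0.268 with an estimated correlation; 9 rose and 1 fell adjusted over the list alone). Acute phase and coagulation genes rose in 15 of 27 and fell in 3, with the copper protein ceruloplasmin, Cp, at 1.74 ± 0.114, the endotoxin-binding protein Lbp at 1.39 ± 0.00625 and Anxa2 at 1.35 ± 0.0628. The 3 falls, named after their values were seen, were Crp at -0.75, the coagulation inhibitor antithrombin, Serpinc1, at -0.71 and the anticoagulant Proc at -0.35, a call lost without mouse 3 (-0.34, adjusted p = 0.0603). Serpinc1 and Proc also lost theirs with exact 0 values kept. The list mean was 0.53 (adjusted p = 9.16e-05, and adjusted p = 0.223 with an estimated correlation; 15 rose and 3 fell adjusted over the list alone).

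Tubular injury genes gave the highest list mean, 1.10, between 1.02 and 1.14 in the 3 mice. Of 33 members 31 rose and 0 fell, including the early response factor Egr1 at 1.85 ± 0.0619, the iron-binding protein Lcn2 at 1.22 ± 0.146 (SD, n = 3) and, as given above, S100a6, Sox9 and Vcam1. The adjusted p was 6.47e-16, and the adjusted p was 0.223 with an estimated correlation; 31 rose adjusted over the list alone, and 12 of the 33 belong to another list. Matrix and fibrosis genes rose in 39 of 51 and fell in 1, Fbln2 at -0.55, named after its value was seen. Without mouse 3 it moved to -0.34 and lost its call (adjusted p = 0.0553), which was also lost with exact 0 values kept. The collagen cross-linking enzyme Loxl2 rose by 1.95 ± 0.12 and Tgfbi by 1.41 ± 0.0503, and Loxl2 moved to 0.69 with exact 0 values kept. The list mean was 0.73 (adjusted p = 8.42e-13, and adjusted p = 0.236 with an estimated correlation; 42 rose and 2 fell adjusted over the list alone). Cell cycle genes rose in 34 of 51 and fell in 3, with the proliferation marker Mki67 at 1.43 ± 0.221, the kinetochore protein Cenpf at 1.36 ± 0.022, the mitotic kinase Cdk1 at 1.32 ± 0.0446 and cyclin Ccna2 at 1.06 ± 0.144. The falls, named after their values were seen, were Nusap1 at -0.69, Ccnd1 at -0.39 and Tyms at -0.36. Ccnd1 and Tyms lost their calls without mouse 3 (-0.31 and -0.30) and moved to -0.18 and -0.17, with no call, when exact 0 values were kept, where Nusap1 lost its call too. The list mean was 0.41 (adjusted p = 2.05e-07, and adjusted p = 0.223 with an estimated correlation; 36 rose and 4 fell adjusted over the list alone).

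Proximal tubule genes were lower in most cases. Of 45 transporters and enzymes, 31 fell and 2 rose, and the list mean was -0.50, between -0.551 and -0.447 in the 3 mice. Besides Slco1a6, the cation transporter Slc22a4 was at -1.40 ± 0.122, Acsm3 at -1.29 ± 0.0813 and Gatm, an enzyme of creatine synthesis, at -1.17 ± 0.117 (SD, n = 3). The 2 that rose, named after their values were seen, were the vitamin D-degrading enzyme Cyp24a1 at 1.02 and the sulfate transporter Slc13a1 at 0.79, which moved to 0.42 and lost its call with exact 0 values kept. The adjusted p was 2.3e-08, and the adjusted p was 0.223 with an estimated correlation; 31 fell and 2 rose adjusted over the list alone.

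Many genes of oxidative metabolism fell too. Of 43 fatty acid oxidation and peroxisome genes, 30 fell and 1 rose, the thioesterase Acot1 at 0.33, named after its value was seen and not passing without mouse 3 (0.35, adjusted p = 0.0514). Catalase, Cat, was at -1.04 ± 0.18, Ehhadh, an enzyme of peroxisomal oxidation, at -1.06 ± 0.225, Ech1 at -0.81 ± 0.157 and Acox2 at -0.75 ± 0.076 (SD, n = 3). Cat, Ehhadh and Ech1 lost their calls with exact 0 values kept. The list mean was -0.42 (adjusted p = 1.02e-07, and adjusted p = 0.223 with an estimated correlation; 32 fell and 2 rose adjusted over the list alone). Of 30 genes of mitochondrial respiration and the TCA cycle, 18 fell and 0 rose, with Sucla2 at -0.93 ± 0.14, Dlat at -0.74 ± 0.0636, the ATP synthase subunit Atp5b at -0.67 ± 0.0741 and Pcx at -0.66 ± 0.128, whose call was lost with exact 0 values kept. The mean was -0.32 (adjusted p = 0.000133, and adjusted p = 0.255 with an estimated correlation; 18 fell adjusted over the list alone). Oxidative stress and glutathione genes fell in 13 of 36 and rose in 4, with the glutathione transferases Gsta3 and Gstm4 at -0.67 ± 0.0719 and -0.67 ± 0.091 and the metallothionein Mt2 at 0.78 ± 0.139, a call also lost with exact 0 values kept. The mean was -0.15 (adjusted p = 0.0362, and adjusted p = 0.255 with an estimated correlation; 14 fell and 4 rose adjusted over the list alone), and the call was lost without mouse 1 (adjusted p = 0.134).

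Of 31 rows below 0 that belong to the proximal tubule, fatty acid and mitochondrial lists and have a second row, 27, or 87.1%, had a second row below 0 as well, against 67.5% of all 1097 such rows. Of 23 rows above 0 of the macrophage, injury and matrix lists, 20, or 87%, had a second row above 0, against 72.9% of all 1286. With 1 row per gene, the farthest from 0, the second row had the same sign in 13 of 17 genes of the lower lists, or 76.5%, against 50.8% of all 707 genes. It did in 10 of 13 genes of the higher lists, or 76.9%, against 56.3% of all 789, and these differences were not tested. The sizes of the changes were not matched. Among rows of any gene with a change of 0.5 to 1, second rows shared the sign of 85.8% of falls and 85.5% of rises. The shares therefore do not show that the lists agreed better than rows of like size.

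Endothelial and mesangial genes rose in 10 of 27 and fell in 0, with the transcription factor Klf4 at 0.94 ± 0.0736, Thy1 at 0.82 ± 0.0636, Fhl2 at 0.70 ± 0.194 and smooth muscle actin, Acta2, at 0.55 ± 0.0474 (SD, n = 3). Among endothelial markers of the list, picked after their values were seen, Eng and Sox18 rose by 0.43 and 0.32. Pecam1, Kdr, Tie1, Flt1, Tek and Emcn did not pass, at 0.13, -0.11, -0.04, -0.01, 0.11 and 0.11. These markers were not followed through the alternatives and are not among the 31 counted above. The call of Fhl2 was lost with exact 0 values kept. The mean was 0.23 (adjusted p = 0.0114, and adjusted p = 0.315 with an estimated correlation; 10 rose adjusted over the list alone), and the call was lost when members of several lists were left out (adjusted p = 0.105). Podocyte genes rose in 5 of 21 and fell in 5, with a mean of -0.05 (adjusted p = 0.695; 7 rose and 6 fell adjusted over the list alone). Myh9, a myosin of many cell types, rose by 0.87 ± 0.0449, the transcription factor Foxc2 fell by 0.59 ± 0.252. The peptidases Enpep and Mme, which proximal tubules also make, fell, to -0.58 ± 0.0754 and -0.39 ± 0.0202. So did Dpp4, another peptidase of proximal tubules, to -0.67 ± 0.48. Dpp4 was picked after its value was seen and was not followed through the alternatives. Nephrin, Nphs1, named after its value was seen, fell by 0.42 ± 0.265, and moved to -0.26 without mouse 2, where its call was lost (adjusted p = 0.0666). Foxc2 and Nphs1 lost their calls with exact 0 values kept. Distal nephron and collecting duct genes fell in 14 of 38 and rose in 7, with the water channel Aqp4 at -1.38 ± 0.13, the calcium-binding protein S100g at -1.23 ± 0.0895 and the anion exchanger Slc4a1 at -1.23 ± 0.191. Keeping exact 0 values moved S100g and Slc4a1 to -0.49 and -0.77, where both lost their calls (adjusted p = 0.0717 for each). That list did not pass in camera (mean -0.18, adjusted p = 0.22), while fry gave an adjusted p of 0.0295. Adjusted over the list alone, 14 fell and 7 rose.

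Other blood cell lists did not pass in camera with its preset correlation. Fry, which does not compare a list with other genes, gave adjusted p-values of 0.0202 for neutrophil, 0.0281 for erythroid and 0.0295 for T and NK cell genes. It gave 0.0952 for B and plasma cell genes. Neutrophil genes rose in 6 of 17 and fell in 4 (mean 0.23, adjusted p = 0.189; 7 rose and 4 fell adjusted over the list alone). S100a9 was at 1.48 ± 0.162, the receptor Fpr2 at 0.82 ± 0.114 and S100a8 at 0.55 ± 0.132 (SD, n = 3). Keeping exact 0 values moved S100a9 to 0.97 and ended the call of S100a8. T and NK cell genes rose in 6 of 21 and fell in 3 (mean 0.13, adjusted p = 0.134; 7 rose and 3 fell adjusted over the list alone). The co-receptor Cd8a was at 0.99 ± 0.157 (0.53 with exact 0 values kept), the cytokine receptor Il7r at 0.88 ± 0.079 and the cytokine Il17a at -0.86 ± 0.0708. Falls also included Ly6g at -0.51 and Cxcr2 at -0.31 among neutrophil genes and Ifng at -0.93 among T and NK cell genes. Ly6g and Ifng were picked after their values were seen, were not followed through the alternatives and are not among the 31 counted above. B and plasma cell genes rose in 5 of 12 and fell in 1 (mean 0.17, adjusted p = 0.188; 7 rose and 2 fell adjusted over the list alone). Cd72 was at 1.16 ± 0.292, Sdc1 at 0.39 ± 0.19, Vpreb3 at 0.28 ± 0.204 and Tnfrsf17 at -0.27 ± 0.187. The calls of Vpreb3 and Tnfrsf17 were lost without mouse 2 (0.24 and -0.25) or mouse 3 (0.21 and -0.19), and that of Tnfrsf17 also without centring (adjusted p = 0.0508). All 4 lost theirs with exact 0 values kept, where Tnfrsf17 moved to -0.13. Erythroid and blood genes rose in 3 of 8 and fell in 3 (mean -0.15, adjusted p = 0.28; 3 rose and 4 fell adjusted over the list alone). Car1 was at -1.66 ± 0.17, the erythroid factor Klf1 at -1.26 ± 0.174 and the platelet gene Pf4 at 2.19 ± 0.343. Without Pf4 the mean of the other 7 was -0.49, and the globin Hbb-b2, named after its value was seen, was at 0.80 ± 0.686, a call lost without mouse 2 or mouse 3 (0.53 and 0.69) or with exact 0 values kept (0.46). Alas2, also named after its value was seen, was at 0.29 ± 0.156, a call lost in the same settings (0.21, 0.31 and 0.31). Ribosomal protein genes rose in 6 of 23 and fell in 0 (mean 0.09, adjusted p = 0.252; 6 rose adjusted over the list alone). Rpl19 was at 0.60 ± 0.0236, Rpl15 at 0.45 ± 0.188, Rps18 at 0.38 ± 0.0905 and Rpl10a at 0.33 ± 0.0235, and Rps18 and Rpl10a lost their calls without mouse 3 (0.33 and 0.34). Rpl15 and Rps18 lost theirs with exact 0 values kept.

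The lists of surrounding tissue and of sex had means below 0. Adipose, adrenal and muscle genes fell in 6 of 12 and rose in 0, with Myh1 at -1.95 ± 0.368, lipoprotein lipase, Lpl, at -1.19 ± 0.297, the steroid electron carrier Fdx1 at -0.88 ± 0.0303 and the muscle protein Tnnt3 at -0.52 ± 0.0675 (SD, n = 3). The mean was -0.48 (adjusted p = 0.00998, and adjusted p = 0.236 with an estimated correlation; 6 fell adjusted over the list alone), and the call was lost when exact 0 values were kept (adjusted p = 0.139), as were those of Myh1 and Lpl, while Tnnt3 moved to -0.25. Sex-linked and androgen-dependent kidney genes fell in 8 of 12 and rose in 2, with Acsm3 as above, Cyp2d9 at -0.72 ± 0.274, Odc1 at -0.49 ± 0.0934 and Gusb at 0.46 ± 0.1. With exact 0 values kept Cyp2d9, Odc1 and Gusb lost their calls, and Gusb moved to 0.24. Of the sex-linked members, named after their values were seen, the X-linked Xist rose by 0.37 ± 0.286 and the Y-linked Kdm5d fell by 0.20 ± 0.0312, while the Y-linked Uty stood at 0.19 ± 0.23 and did not pass. Uty moved to 0.06 without mouse 1, to 0.07 with array weights and to 0.10 with exact 0 values kept. The call of Xist was lost without mouse 2 or mouse 3 (0.27 and 0.31) and with exact 0 values kept. That of Kdm5d, at an adjusted p of 0.0498, was lost without mouse 1, mouse 2 or mouse 3 (adjusted p = 0.0623, 0.177 and 0.216). It was also lost without centring (0.0651), with scaled arrays (0.0501), a robust prior (0.0503), ratios on 2 arrays (0.0607), exact 0 values kept (0.0528) and the unmoderated test. The sex of the mice is not given in the sources used here, and the list mean was -0.28 (adjusted p = 0.0432, and adjusted p = 0.268 with an estimated correlation; 8 fell and 2 rose adjusted over the list alone). The call was lost without mouse 1 or mouse 3 (adjusted p = 0.0519 and 0.0639) and when members of several lists were left out (adjusted p = 0.125).

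**Figure D3:**
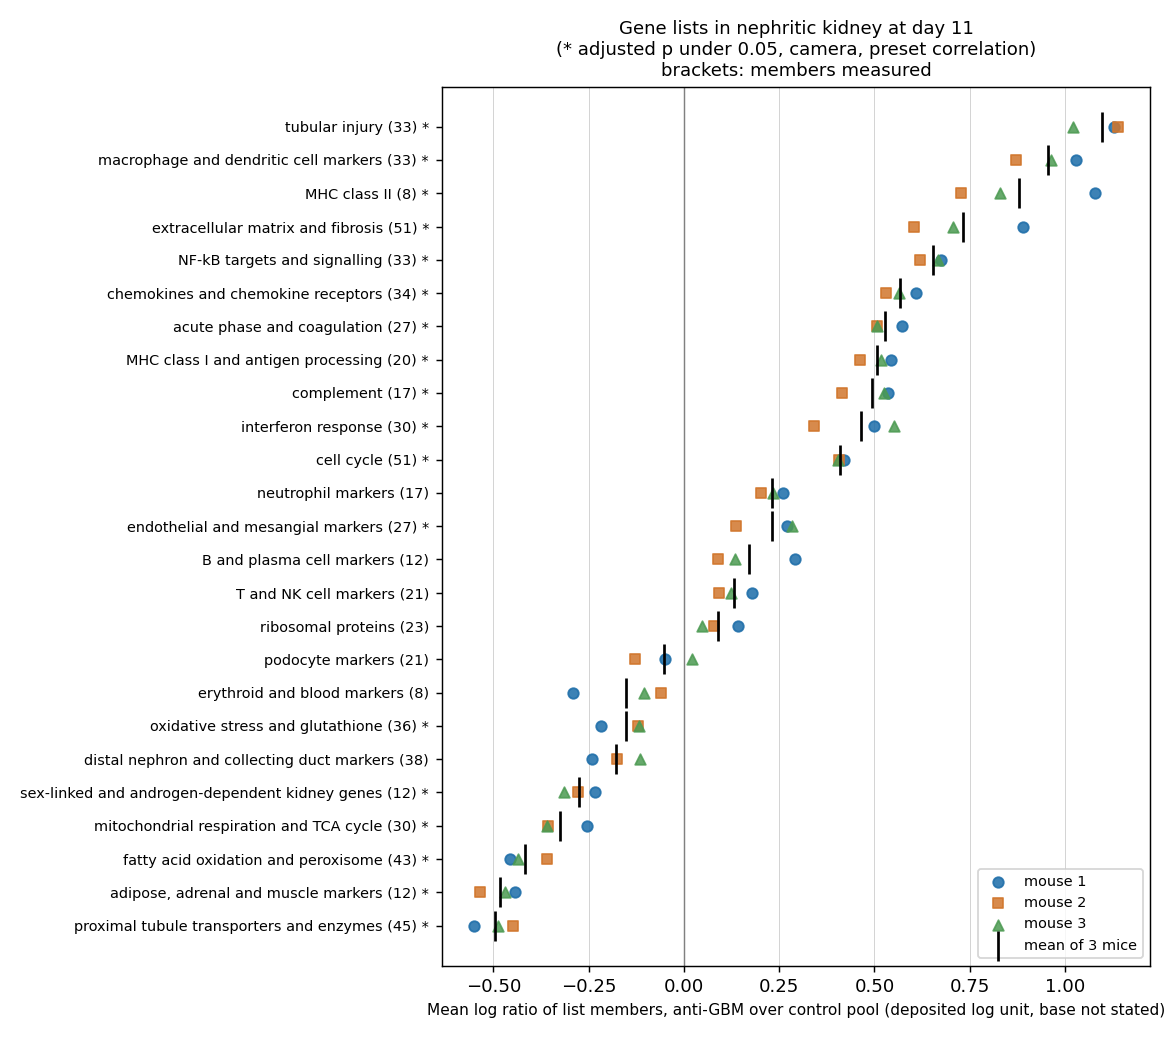
Mean log ratio of the measured members of each of the 25 gene lists (x axis, deposited log unit), with 1 symbol per mouse, a bar at the mean of 3 mice and the number of measured members in brackets. Asterisks mark the 18 lists with an adjusted p under 0.05 in camera with its preset correlation, from tubular injury at 1.10 to proximal tubule genes at -0.50.

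Of the 25 lists, 12 were higher, 6 were lower and 7 did not pass in camera with its preset correlation. No call held with an estimated correlation, where 0 of 25 lists passed and the lowest adjusted p was 0.223. Both the estimate and the test then rest on 2 residual degrees of freedom, which leaves little power. The estimate lay below the preset 0.01 for NF-kB (0.00897), cell cycle (0.00703) and oxidative stress genes (0.00339), whose calls were lost too. It was also below 0.01 for adipose, adrenal and muscle genes (-0.0311) and sex-linked genes (-0.0878), with the same loss. The lost calls therefore do not tell whether correlation among members undoes a list. The list mean had the same sign in all 3 mice in 24 of the 25 lists, the podocyte list being the exception.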

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

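Keeping exact 0 as a ratio and leaving out the run of low rows were chosen after the data were seen; all other alternatives were planned. The planned scaling function failed on these ratios, and the one used sets equal median absolute values in place of median absolute deviations. The count of changed features, 3638, was 0 in the unmoderated one-sample test (3060 at an unadjusted p under 0.05, smallest adjusted p 0.0541), which follows from 2 residual degrees of freedom without a shared prior. It was 986 with exact 0 kept, of which 900 were shared, and between 2202 and 4193 with each mouse left out, the lowest without mouse 3; the cause was not tested. The other settings gave between 2836 and 5194. Lower calls outnumbered higher ones except without centring (51.9% higher), with exact 0 kept (55.7%) and without mouse 2 (50.7%), the unmoderated test having none. With exact 0 kept, r between mice was 0.722, 0.764 and 0.836.

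With an estimated correlation 0 lists passed. The adjusted p was 0.223 for MHC class I, NF-kB, macrophage, tubular injury, acute phase, proximal tubule, fatty acid and cell cycle genes, 0.228 for chemokines, and 0.236 for matrix and for adipose, adrenal and muscle genes. It was 0.255 for mitochondrial and oxidative stress genes, 0.268 for complement and sex-linked genes, 0.283 for interferon and 0.315 for MHC class II and endothelial genes. Fry, which does not compare a list with other genes, gave 0.0202 for neutrophil, 0.0281 for erythroid and 0.0295 for T cell and for distal nephron genes. Without members of several lists, endothelial genes gave 0.105 and sex-linked genes 0.125. With exact 0 kept, adipose, adrenal and muscle genes gave 0.139. With each mouse left out, oxidative stress genes ranged from 0.0156 to 0.134 and sex-linked genes from 0.0396 to 0.0639.

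No list and none of the 110 genes named by the rule changed direction in the alternatives run. All 110 lost the threshold in the unmoderated test and 38 with exact 0 kept. The latter moved 19 of them by over 1.5 times. A call could be lost there with no 0 in the gene's own rows, as for Col3a1. Without mouse 3, 4 lost it (Tnfrsf17, Vpreb3, Rps18 and Rpl10a), and without mouse 2, Tnfrsf17 and Vpreb3; without centring Tnfrsf17 did. Of the 31 genes named after their values were seen, Ciita, which did not pass, ranged from -0.17 to 0.00367 with each mouse left out and was above 0 without mouse 2. No other changed direction in the alternatives run. Of these 31, 22 lost the threshold with exact 0 kept and 29 in the unmoderated test. Without mouse 3, 12 lost it (Cxcr2, Ikbkg, C9, Proc, Fbln2, Ccnd1, Tyms, Acot1, Hbb-b2, Alas2, Xist and Kdm5d). Without mouse 2, 7 did (Ikbkg, C9, Nphs1, Hbb-b2, Alas2, Xist and Kdm5d). Kdm5d, at an adjusted p of 0.0498, lost it in most alternatives, with any mouse left out included. Without mouse 2, C9, Nphs1 and Hbb-b2 moved to -0.23, -0.26 and 0.53, and without mouse 3 Fbln2 moved to -0.34. The count of genes changed at least 2-fold was not run, since the log base is unknown. No paired analysis was possible because there was 1 group of mice and 1 control pool.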

Other observations

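All tests in this part were chosen after the data were seen, except that the test of neighbouring falls outside the run was written down before its result. Gene families, taken as the 113 symbol stems with at least 8 measured members, give a further grouping that overlaps the fixed lists in part. Of the 9 Ms4a genes, membrane proteins many of which mark leukocytes, 8 rose and 0 fell (mean 0.87, camera adjusted p = 0.000312), with Ms4a6c at 1.46 ± 0.106 and Ms4a4c at 0.91 ± 0.0608 (SD, n = 3). The adjusted p was 0.916 with an estimated correlation, for this family and for each one below. Of 9 aldo-keto reductases, 8 fell and 1 rose (mean -0.61, adjusted p = 0.0251, and 0.916 as an adjusted p with an estimated correlation), with Akr1c18, which breaks down progesterone, at -1.07 ± 0.308, and Akr1b8, the exception, at 0.35 ± 0.0793. Of 12 aldehyde dehydrogenases, 8 fell and 1 rose (mean -0.35, adjusted p = 0.0365, and again 0.916), with Aldh6a1, of valine breakdown, at -1.06 ± 0.192. Akr1c18, Akr1b8 and Aldh6a1 lost their calls with exact 0 values kept.

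Kallikrein genes fell in 7 of 9 (mean -0.42, adjusted p = 0.0268, and adjusted p = 0.916 with an estimated correlation), with Klk1b21 at -0.84 ± 0.332, a call lost with exact 0 values kept, but the Klk1b genes are near-identical copies and their separate values are uncertain. Mitochondrial ribosome genes named Mrps fell in 8 of 17 and rose in 0 (mean -0.22, adjusted p = 0.0251, and again 0.916). Solute carriers fell in 59 of 140 and rose in 20 (mean -0.21, adjusted p = 0.0106, and again 0.916). The Ccl, Col, Cd, Il and Cxcl stems were higher (adjusted p = 0.00387, 0.0106, 0.0173, 0.0187 and 0.0309) and share members with fixed lists. So do the Ms4a, solute carrier and aldo-keto reductase stems, through genes such as Ms4a6d, Slc34a1 and Akr1c21. These 11 stems passed with the preset correlation and kept their direction without centring and with scaled arrays. None passed with an estimated correlation, where every adjusted p was 0.916. With 2 residual degrees of freedom that setting does not tell whether correlation among members undoes these calls.

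A run of 16 neighbouring row IDs had low ratios side by side, for genes with no evident common role such as Hes1, Lhx1, Sdc3 and Akt2. The run held 10 rows of -1 or less, against at most 5 in 10000 shuffles of the row order (permutation p = 1e-04, the smallest they can give). The window was given the length of the run, which was picked for its low rows, so this p describes the run and is no separate support. In the 4 genes with a low row in the run and other rows elsewhere, the other rows lay higher by 1.93 (SD 0.237), which argues against lower expression of those 4; Nxf1, not low in the run, had another row at -1.15, and over all 5 genes the difference was 1.31 (SD 1.4). All 3 arrays had a median under -1 over the run (-1.99, -2.09 and -1.57), which argues against a defect of a single hybridisation. A fault shared by neighbouring clones or print positions may explain the run and stays open.

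Large falls outside the run were often not shared by a second row of the gene, as in Kl at -1.83 and -0.33, Trhr at -1.76 and 0.18 and Ncam1 at -1.43 and 0.54. Symmetric noise picked by its size cannot be told apart from other causes: it would leave as many rises as falls unshared, and with 1 row per gene 27 falls and 16 rises were (exact binomial test, two-sided, p = 0.126). A positional fault may play a part in falls outside the run. Of all 148 such falls, 18 had another within 2 IDs, against a median of 6 in 1000 shuffles (permutation p = 0.002). None of the 9 neighbouring pairs were of the same gene. Of 248 rises, 17 had another within 2 IDs (median 15, permutation p = 0.36). Only 34 of the 148 falls had a second row, so the unshared falls themselves were not tested for position. Second rows shared the sign of 85.8% of falls and 85.5% of rises of 0.5 to 1 in size, and 61.4 and 66.5% were at least 0.5 times as far from 0; of changes of 0.25 to 0.5, they shared the sign of 76.3% of falls and 86.9% of rises. Other causes, such as clones that hold another sequence than their name, were not tested.

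The mean of the macrophage and dendritic cell list was above 0 in all 3 mice, with 29 of 33 members higher (adjusted p = 1.02e-14, and adjusted p = 0.223 with an estimated correlation). A lower share of tubule RNA would raise the markers of every other cell type alike, and the macrophage list exceeded the podocyte list by 1.01 (SD 0.0695 over mice). The podocyte list is a weak yardstick, since it holds Enpep, Mme and Dpp4, which proximal tubules also make, and the glomerulus is the site of this injury. The endothelial and mesangial list had a mean of 0.23, with 10 of 27 members higher and 0 lower, against 0.95 for the macrophage list. Its endothelial markers did not all rise, since Eng passed while Pecam1 and Kdr did not. An equal rise as the whole cause is argued against for these lists, while a part played by a lower tubule share stays open. Blood left in the kidneys cannot be told apart from infiltration here, because the erythroid list had a mean of -0.151 (SD 0.123) over members that went both ways. The platelet gene Pf4, at 2.19 ± 0.343, raises that mean, which was -0.486 (SD 0.188) without it. Itga2b, another platelet gene of the list, was at -0.19 and did not pass (limma adjusted p = 0.052). The globin Hbb-b2 and Alas2 were at 0.80 ± 0.686 and 0.29 ± 0.156, against Car1 at -1.66 ± 0.17. Car1 rested on 1 row, within 2 IDs of the Trhr row whose fall a second row did not share, so its value is uncertain. More macrophages in the nephritic kidney, or higher expression in those already there, may both give this pattern, and the design does not separate them.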
